A study of Caenorhabditis elegans with 4 samples.

How the data were processed

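Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in 4 libraries of strain OP81 at the L3 stage, 2 ChIP replicates and 2 inputs. Per the labels' protocols, synchronised larvae were grown in liquid culture at 20 °C, fixed in 2% formaldehyde for 30 min, and their chromatin was sheared to between 200 and 800 bp; input DNA was from the same preparation as the ChIP of its number. Samples were grouped as EOR-1 ChIP (n = 2) and input (n = 2) by the labels.

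The files used were peak lists and per-read alignments. Per the file headers, peaks were on the WormBase WS180 build and came from PeakSeq, 1 list per ChIP replicate, and the deposited value of each peak is a q-value, corrected for multiple tests; in both lists it was under 0.01. Version and settings of PeakSeq, whether duplicates were removed, and how flow cells were joined are not given in the sources used here. The q-values are the authors' and were used to rank and filter peaks within a list and to correlate the lists. The alignments are in the extended format of ELAND per the deposited file names, 1 line per read of 30 bases, with the number of placements at 0, 1 and 2 mismatches and positions for at most 10 placements. Each ChIP library had been run on 2 flow cells and each input on the first of them.

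From the alignments, reads with 1 printed placement were tallied at its lowest coordinate, the flow cells of a library being summed. Reads with no placement made up 70.9% of ChIP replicate 1 on the first flow cell and 85.7% on the second, 60.3% and 84.4% of ChIP replicate 2, 76.9% of input replicate 1 and 81.0% of input replicate 2. On the second flow cell 9.14% and 8.17% of ChIP reads began with an uncalled base. Mitochondrial DNA took 0.123%, 0.354%, 0.441% and 3.49% of placed reads in ChIP 1, ChIP 2, input 1 and input 2, and was left out of the nuclear scaling and of the chromosome comparison. The distance at which reads of opposite strands met most often was 170 and 160 bp in ChIP and 90 and 130 bp in the inputs, and summits were found with a shift of 82 bp. Because ELAND prints mismatched reference bases, the reference was spelled out from the reads wherever they fell, which gave 61393047 bases, 61.2% of the span, with 0 conflicts in 86006013 bases seen more than once.

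The main test used 1 kb tiles with a mean of at least 10 reads per library, 24004 of 100282, with limma voom 3.58.1 in R 4.3.3, all 4 libraries, group as the only term, size factors by the median of ratios, and a Benjamini-Hochberg adjusted p under 0.05. The tallies were made here from alignments and were in no deposited column, so limma was used in place of a negative binomial tool. Replicate numbers pair the libraries because the labels give each input as DNA of the same preparation; as a check, the replicate differences of log2 reads in ChIP and in input had a correlation of 0.0388 across 24004 tiles. The fit with the replicate number as a block was an alternative. On simulated data with the libraries' own depth, limma called 1% of tiles changed 2-fold and 33% of those changed 4-fold. It made 0 false higher and 5 false lower calls among 21782 unchanged tiles. The binomial test in both replicates called 1% and 44%. The simulation gave ChIP and input the same profile apart from 200 changed tiles, with a dispersion set by hand. In the data 21.8% of tested tiles overlapped a shared region, so its false calls cannot vouch for the split of higher and lower tiles.

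A shared region is the union of overlapping peaks of both replicates, with at least 1 bp in common. Random placements were drawn 1000 times within chromosomes. Ratios of ChIP to input used reads divided by the size factors, with a pseudocount of 1 on the log2 scale, and ratios without a pseudocount have exact conditional binomial 95% intervals. The ratios of the chromosome X region without a replicate 2 peak used library totals instead, with log-normal 95% intervals. Ratios of repeats among reads without a single placement have intervals of that kind too. Shares of reads in shared regions have exact binomial 95% intervals, and other shares have Wilson 95% intervals. A ratio against an input at 0 was computed against 3 reads per library. The intervals and these bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

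The motif test compared windows of 100 bp either side of a shared region's centre with windows 1 kb to each side that lie outside all peaks, by Fisher's exact test, using windows with at least 80% of bases spelled; 3714 of 3738 centres and 2328 of 6331 side windows were used. The scan of 8-mers used the same windows, by Fisher's exact test with the smaller tail doubled. To test the scan, the side windows were split at random into 2 parts of 1164, and 10 words were implanted in 1 part. The scan recovered 2 of 10 at 1.5% of windows per word and 10 of 10 at 5%, with 0 calls without implants. Random parts do not differ in GC content as centres and side windows do, so those 0 calls do not bear on false calls between these. Shared regions per chromosome were compared with the share of input reads by exact binomial tests, adjusted over the chromosomes. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

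The rule for named items, fixed before the data were examined, took 25 genes by the ratio at a promoter peak, or regions named by position where no matching reference was at hand. The reference annotation in use is on another build than WS180, so the second form applied: the 25 shared regions with the largest mean log2 ratio of ChIP to input. Other regions named, such as those with the smallest q-values, the widest one, the region on chromosome X and the segment on chromosome IV, were chosen after their values were seen. For the same reason peaks at promoters, the enrichment of fixed gene lists and the read depth of unc-119 were not run. The depth planned for the tagged gene was measured over 5 kb around the place where the bases after the tag in 1 read fall. Whether that place is the tagged gene stays open. The tag words searched for and the patterns for other factors were chosen after the reads were seen.

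Alternatives covered the replicate block, scaling by library totals, low-count filter, tile width, duplicates, flow cell, voom weights, a binomial test, each library left out, overlap rules, the stronger 50% of peaks by q-value, pseudocount, summed inputs, motif mismatches and window size, and the chromosome background. Added after the data were seen were scaling by nuclear reads outside peaks for tiles and ratios, the block together with library totals, a filter on ChIP reads alone (a mean of at least 15), and the ChIP summit as the motif's centre.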

Results

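The series measured where EOR-1 sat on chromatin in whole Caenorhabditis elegans larvae at the L3 stage. EOR-1 is a BTB zinc finger protein, related to PLZF, known from Ras and Wnt signalling. Strain OP81 carried EOR-1 fused at its carboxy end to GFP and a 3xFLAG tag, and chromatin was pulled down with an antibody against GFP. There were 4 libraries in 2 groups, 2 EOR-1 ChIP replicates and 2 inputs, each input being chromatin of the same preparation without the pull-down. EOR-1 ChIP replicate 1 held 5115928 reads, of which 1012559 had a single placement in the genome, and replicate 2 held 4858949 reads with 1322728 placed once. Input replicate 1 held 3364161 reads with 629033 placed once, and input replicate 2 held 3209096 reads with 502516 placed once. The authors' peak lists, 1 per ChIP replicate on the WS180 genome build, held 5113 and 5561 peaks with median widths of 304 and 305 bp. All positions are given on WS180, and regions are named by position because genes were not placed on that build here. Intervals cover counting error alone.

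The tagged protein was looked for first, since the strain's label says that EOR-1 was fused to the tag. Among reads without a placement, words from the 3xFLAG tag occurred in 2 reads of ChIP replicate 1, 9 of ChIP replicate 2, 5 of input replicate 1 and 2 of input replicate 2. The longest stretch read beyond the end of the tag, TAATAAATATAGTCC, had 1 place in the sequence that the reads spelled out, IV:4793371-4793385 on the minus strand; eor-1 is a gene of chromosome IV. That place lay inside a 38 kb segment, IV:4786001-4824000, which was 0.0379% of the genome and had many more reads than the rest of its chromosome in all 4 libraries. The segment's read depth was taken relative to the median of the 1 kb bins of chromosome IV that held a read. It was 16.7 and 20.3 in input replicates 1 and 2, and 17.9 and 20.3 in ChIP replicates 1 and 2. Over 5 kb around the place of the stretch, IV:4790871-4795871, depth in the inputs was 18.6 ± 4.49 times the median of all 1 kb bins (SD, n = 2). The segment's values and this one have different medians below them, so they are not on 1 scale. No shared peak was called in the segment, and 1 region was called there in replicate 1. This place rested on 1 read of input replicate 1. Of the other reads with at least 12 bases beyond the tag, one, also of input replicate 1, had 22 places for its 12 bases, this one among them, and one of ChIP replicate 2 had 5 places for its 14 bases, none of them in the segment.

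**Figure D1:**
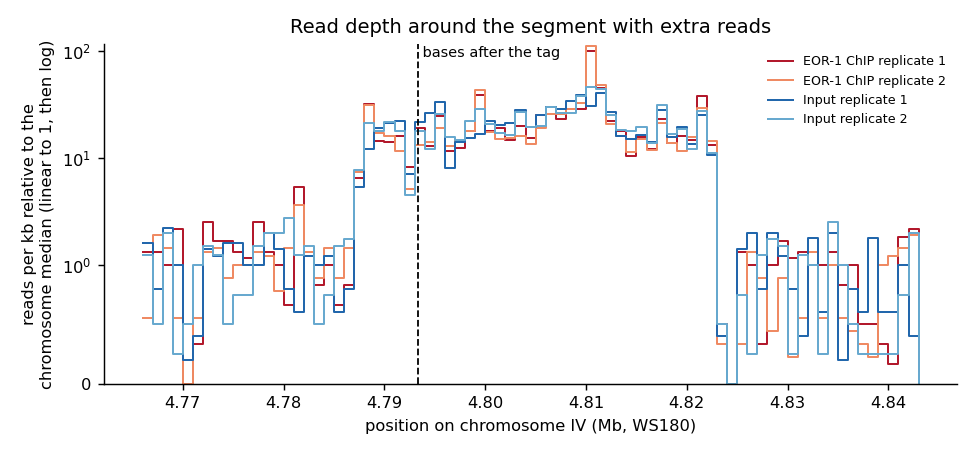
Reads per kb relative to the median of chromosome IV (vertical axis, linear to 1 and then log) against position in Mb (horizontal axis), 1 line per library. Depth rose together in the 4 libraries over IV:4786001-4824000, and the dashed line marks the single place of the longest stretch read beyond the tag. The plot uses the median of all 1 kb bins. Relative to the median of bins that held a read, the segment had 16.7 and 20.3 in the inputs.

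The first comparison asked where immunoprecipitated chromatin exceeded its own input. Of the 3738 regions with a peak in both replicates, the region I:5637405-5638169 had 211 and 269 ChIP reads against 5 and 3 input reads, ratios of 19.6 (95% interval 8.26 to 60.9) and 26.7 (9.05 to 130.4) after scaling. The region V:9342992-9344725 had 769 and 772 ChIP reads against 23 and 34 input reads, ratios of 15.5 (10.3 to 24.6) and 6.77 (4.80 to 9.85). At III:12612207-12613801, 630 and 514 ChIP reads stood against 20 and 22 input reads, ratios of 14.6 (9.38 to 24.1) and 6.96 (4.55 to 11.2). At I:5379336-5380413 the ratios were 47.1 (12.9 to 391.3) and 5.07 (2.60 to 11.3). The shorter regions I:9625905-9626259, III:2597029-2597437 and IV:3338719-3339062 lay close together between replicates, with mean log2 ratios of 3.35 ± 0.19, 3.44 ± 0.17 and 3.57 ± 0.18 (SD, n = 2, with a pseudocount of 1 read).

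These are among the 25 shared regions with the largest mean log2 ratio, of which 6 were on chromosome I, 4 on II, 5 on III, 7 on IV, 2 on V and 1 on X. In 15 of the 25, at least 1 input had no read, so that their ratio in that replicate is a lower bound set by 3 reads per library. V:9088641-9089293 was at least 20.9-fold higher in ChIP than in input in replicate 1, and 5.56-fold higher (2.48 to 15.5) in replicate 2. IV:6756124-6756804 was 12.1-fold higher (3.98 to 59.7) in replicate 1, with 3 input reads, and at least 10.7-fold higher in replicate 2. IV:11068285-11068622 and IV:5806999-5807239 had no read in either input, and were at least 4.79-fold and 2.63-fold higher in replicate 1 and at least 1.79-fold and 1.49-fold higher in replicate 2. Over all 3738 shared regions, the median log2 ratio of ChIP to input was 1.79 in replicate 1 and 0.98 in replicate 2, with SDs across regions of 0.81 and 0.78, and ChIP was above input in 3735 and 3476 of them. Ranking by ratio favours regions with few input reads. The size of every ratio depends on the scaling: with nuclear reads outside peaks, a scaling added after the data were seen, ratios without a pseudocount were 1.62 times as large in replicate 1 and 1.41 times in replicate 2, and with library totals 1.34 and 1.27 times.

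**Figure D2:**
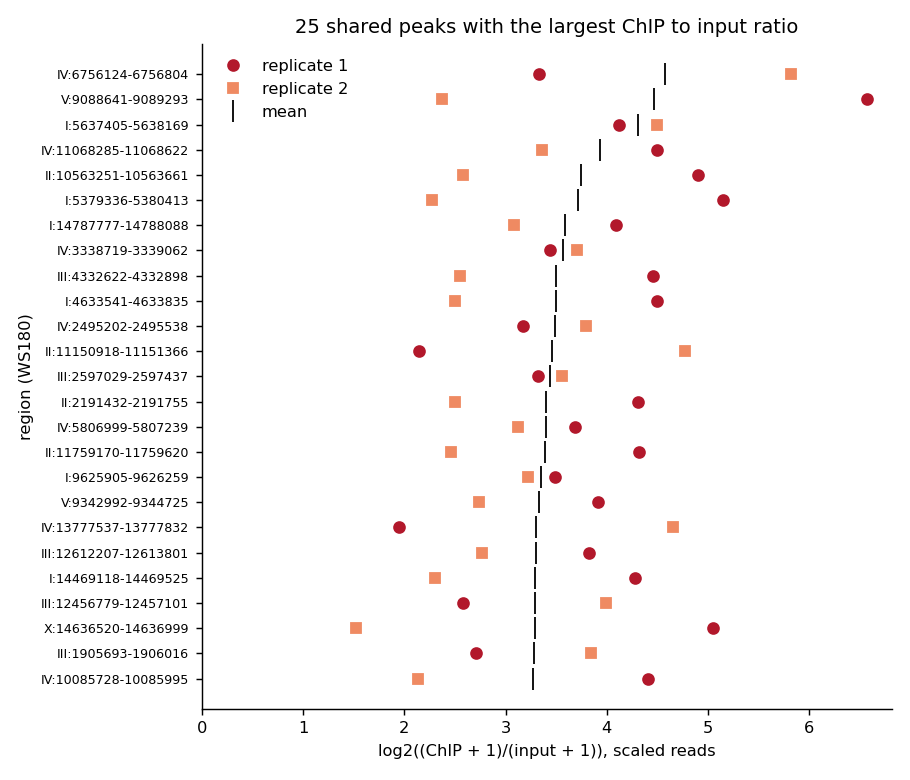
Log2 ratio of scaled ChIP to input reads, with a pseudocount of 1 (horizontal axis), in the 25 shared regions with the largest mean (vertical axis), with circles for replicate 1, squares for replicate 2 and lines for their mean. The means run from 3.27 to 4.58, and points of the 15 regions with an input at 0 depend on the pseudocount.

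The series description gives agreement between the replicates as its measure of quality, and the peak lists were compared on that question. X:16929167-16932008 had the smallest q-values on average, 1.26e-174 in replicate 1 and 3.99e-130 in replicate 2, and 972 and 876 ChIP reads against 50 and 44 input reads. Next came V:9342992-9344725, III:9050947-9055227, III:8443333-8447327 and IV:17277067-17281704, the last with 707 and 831 ChIP reads against 62 and 58 input reads. The widest shared region, II:10541852-10552730, spanned 10879 bp and held 951 and 1315 ChIP reads against 112 and 164 input reads. Of the replicate 1 peaks, 3818 of 5113 had at least 1 bp in a replicate 2 peak, 74.7% (Wilson 95% interval 73.5 to 75.8), and of the replicate 2 peaks 3767 of 5561 did, 67.7% (66.5 to 69.0). When the replicate 2 peaks were placed at random within their chromosomes 1000 times, 4.33% of replicate 1 peaks were met on average and at most 5.48%, so that the permutation p = 0.001, the smallest that this number of placements can give. Among the 1000 peaks with the smallest q-values, 99.9% of replicate 1 and 99% of replicate 2 had a partner among all peaks of the other.

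The 3738 shared regions covered 1953633 bp, 1.95% of the genome spanned by reads. A further 1295 regions had a peak in replicate 1 alone and 1794 in replicate 2 alone. Median log2 ratios in the regions of replicate 1 alone were 1.39 in replicate 1 and 0.34 in replicate 2, and in those of replicate 2 alone 0.71 and 0.77. Across shared regions, which are not independent replicates, Spearman's rho between the 2 replicates' deposited q-values was 0.735. The order of regions by the ratio of ChIP to input, by which the 25 regions were named, was much less alike between replicates.

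One region stood apart among those in a single list. X:11603799-11607670 had the smallest q-value of replicate 1, 5.58e-289, and was not among the replicate 2 peaks used here, but it held many ChIP reads in both replicates, 1400 and 1667 in ChIP against 36 and 43 in input. With duplicates removed, 956 and 1104 ChIP reads stood against 36 and 41 input reads, so ratios from all reads are higher than without duplicates. Scaled by library totals, the ratio of ChIP to input was 24.2 (95% interval 17.4 to 33.6) in replicate 1 and 14.7 (10.9 to 19.9) in replicate 2. Median-of-ratios scaling, used for the regions above, gives lower ratios. Those by library totals are 1.34 and 1.27 times as large in replicates 1 and 2. The next smallest q-value of an unshared region was 5.01e-21, at IV:12033539-12036572, in replicate 2.

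**Figure D3:**
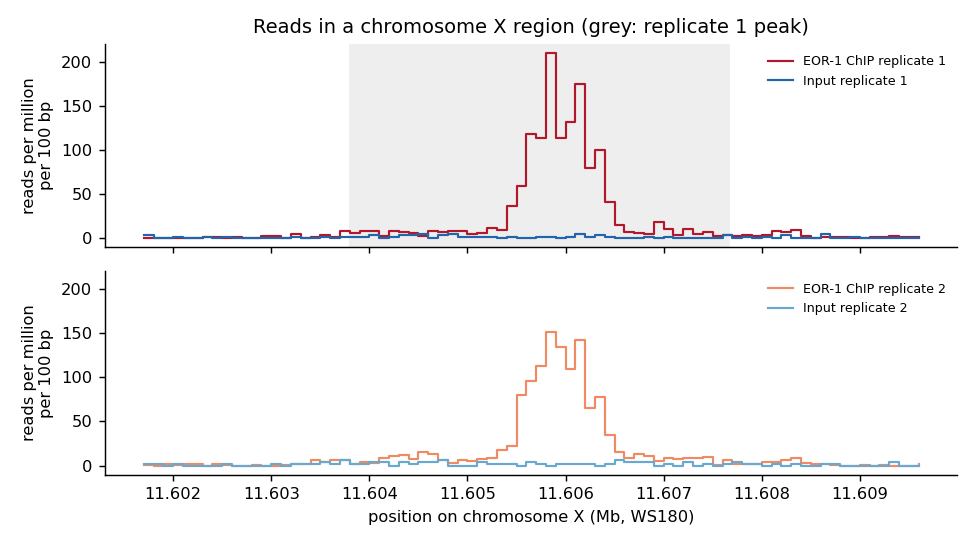
Reads placed once, in RPM per 100 bp (vertical axes), against position on chromosome X in Mb (horizontal axis), for ChIP and input of replicate 1 (upper panel) and replicate 2 (lower panel), with the replicate 1 peak in grey. ChIP reads rose in the same place in both replicates, with 1400 and 1667 reads in the region against 36 and 43 in the inputs.

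Shared regions held a larger part of the reads in both ChIP libraries than in their inputs. They took 18% of placed reads in ChIP replicate 1 (exact binomial 95% interval 18 to 18.1) and 15.9% in ChIP replicate 2 (15.9 to 16). Their part of the input reads was 3.5% in input replicate 1 (3.46 to 3.55) and 5.94% in input replicate 2 (5.88 to 6.01), both above the 1.95% of the genome that they cover. ChIP exceeded its input 5.15-fold in replicate 1 and 2.68-fold in replicate 2, a mean of 3.91 ± 1.75 (SD, n = 2). The regions were called on these same reads, so the excess measures its size and is no independent test.

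Across the genome in 1 kb tiles, reads were higher in ChIP than in input in 777 of 24004 tested tiles and lower in 1061 (limma voom on all 4 libraries, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of the 777 higher tiles, 774 overlapped a shared region, 99.6% (98.9 to 99.9), against 21.8% of all tested tiles; tiles and regions rest on the same reads, so this overlap is no independent test. The higher tiles had a median log2 fold change of 1.56, with median read numbers of 89 and 103 in ChIP and 11 and 13 in input. Of the 1061 lower tiles 7 overlapped a shared region, 0.660% (0.320 to 1.36), with median read numbers of 10 and 13 in ChIP and 13 and 10 in input. The number of lower tiles depended on the scaling: with the median of all tiles at -0.08 on the log2 scale the split was 777 higher and 1061 lower, with library totals (median 0.33) it was 1542 and 202, and with nuclear reads outside peaks (median 0.56), a scaling added after the data were seen, it was 2725 and 131. With the replicate number as a block the counts were 1190 and 3130. Without ChIP replicate 1 limma called 0 tiles either way, with 1326 higher and 2731 lower at an unadjusted p under 0.05. Without ChIP replicate 2 it again called 0, with 1519 and 1993 unadjusted. Without input replicate 1 the counts were 106 and 56, and without input replicate 2 they were 366 and 703. A binomial test of each ChIP library against its own input called 385 tiles higher and 51 lower in both replicates, with 1662 higher in replicate 1 and 451 in replicate 2.

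The next comparison asked which sequence lies at the centre of the shared regions, with GAGACGCAG, known as a motif of EOR-1, fixed before the data were examined. The data from which this motif was first derived were not traced here. If they were these or related EOR-1 ChIP data, finding it here is no independent test. In II:11759170-11759620 the motif lay at II:11759414-11759422, 7 bp from the ChIP summit. In III:12612207-12613801 it lay at III:12612545-12612553, 13 bp from the summit, in III:9050947-9055227 at III:9054012-9054020, 34 bp away, and in I:5379336-5380413 at I:5379920-5379928, 47 bp away. It also lay far from summits: in X:16929167-16932008 the nearest site was 114 bp away, in IV:17277067-17281704 it was 211 bp, in III:13070188-13071772 it was 1110 bp and in II:10541852-10552730 it was 3152 bp. The motif or its reverse complement lay within 100 bp of the centre in 456 of 3714 shared regions, 12.3%, and in 22 of 2328 windows of the same size 1 kb to the side, 0.945%, which is 13-fold more often (two-sided Fisher's exact test, odds ratio 14.7, p = 1.56e-72). Per spelled position there were 6.90 sites in 10 kb at centres and 0.454 to the side, and with sequence spelled by input reads alone 8.54 and 0.522. Of 778 sites within 500 bp of a summit, 54.6% were within 50 bp of it. Among 200 shuffled versions of the motif, the median ratio of centres to sides was 1.59 and the highest 10.2, against 14.8 for the motif itself. Regions without the motif made up most of the shared set, since 529 of 3738, 14.2% (13.1 to 15.3), had it within 100 bp of the summit.

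The motif was present in 18.7% (16 to 21.7) of shared regions with the smallest q-values (group 1 of 5 groups by q-value) and in 13% (10.4 to 15.1) of those with the largest (group 5), with 15.7%, 13% and 11.2% in groups 2 to 4. GAGAGAGA was present in 16% (14 to 19.3) of group 1 and 11.8% (9.65 to 14.3) of group 5. GAGACGCAG was at the centre of 12.3% (11.3 to 13.4) of shared regions, 8.86% (7.40 to 10.6) of those of replicate 1 alone and 6.33% (5.26 to 7.60) of those of replicate 2 alone. The ratio of ChIP to input hardly differed with the motif. Regions with 0, 1 and 2 or more copies around the summit had median ratios of 3.46, 3.49 and 3.56 in replicate 1. In replicate 2 these were 1.97, 2.03 and 1.91. Median width was 388, 412 and 496 bp, and 57 regions had 2 or more copies. No test was run on these trends or medians. Within 100 bp of the summit, GAGAGAGA without the motif occurred in 386 shared regions, both in 105 and neither in 2823. Of the 25 named regions 3 held the motif, I:5379336-5380413, II:11759170-11759620 and III:12612207-12613801.

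**Figure D4:**
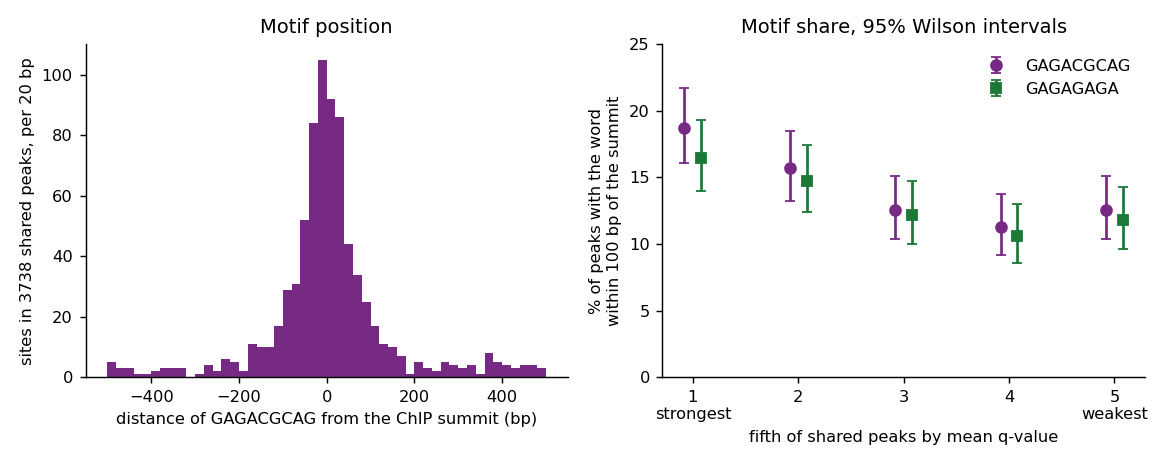
Left, sites of GAGACGCAG per 20 bp (vertical axis) against their distance from the ChIP summit in bp (horizontal axis) in the 3738 shared regions; right, the percent of regions with GAGACGCAG or GAGAGAGA within 100 bp of the summit (vertical axis) in 5 groups by q-value (horizontal axis), with Wilson 95% intervals. Sites gather at the summit, 54.6% of them within 50 bp. The motif's share was 18.7%, 15.7%, 13%, 11.2% and 13% from the group with the smallest q-values to that with the largest.

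A scan of 32877 words of 8 bases was made without regard to the motif. It found 1538 more frequent and 342 less frequent at region centres than to the side (Fisher's exact test with the smaller tail doubled, Benjamini-Hochberg adjusted p under 0.05). The word with the smallest p was AGACGCAG, a part of the motif, in 14.4% of centres and 1.12% of side windows (Fisher's exact test with the smaller tail doubled, p = 1.37e-85). The GA repeat GAGAGAGA followed outside the motif's own words, with 12% against 2.36% (Fisher's exact test with the smaller tail doubled, p = 1.92e-46). Among patterns for other factors, added to the plan, those more frequent at centres were the CA repeat CACACACA (3.97-fold, adjusted p = 8.27e-24), the E2F site (3.76-fold, adjusted p = 5.89e-14), the B box of tRNA genes (8.15-fold, 52 centres against 4 side windows, adjusted p = 2.91e-07), the E-box CACGTG (1.72-fold, adjusted p = 7.93e-06) and the forkhead site (2.00-fold, adjusted p = 2.94e-05). The TCF site (0.687-fold, adjusted p = 0.0229) and the joint Hox and PBC site (0.845-fold, adjusted p = 0.0277) were less frequent, and the GATA site (1.25-fold, adjusted p = 0.116), the Ets site (0.743-fold, adjusted p = 0.306), the AP-1 site (1.04-fold, adjusted p = 0.853) and the heat shock element (1.36-fold, adjusted p = 0.279) did not pass. Side windows were used when reads spelled at least 80% of them, 2328 of 6331, and GC content was 42.8% at centres and 36.7% to the side. Both can move these frequencies.

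The last comparison asked how shared regions were spread over the chromosomes. Chromosome III had the most, 801, where its share of input reads gave 543.7, a ratio of 1.47 (exact two-sided binomial test, adjusted p = 9.58e-29), and it took 21.4% (20.1 to 22.8) of nuclear shared regions. Chromosome I had 737, 1.26 times its share (adjusted p = 1.34e-10). Chromosome V had the fewest for its reads, 488 regions and a ratio of 0.671 (adjusted p = 1.61e-24), followed by X with 580 and 0.846 (adjusted p = 9.04e-06) and II with 496 and 0.866 (adjusted p = 0.000516). Chromosome IV had 635 regions, a ratio of 1.02 (adjusted p = 0.553). These tests take each region as an independent draw. Some regions lie side by side, so the p-values can be too small. In regions per Mb, chromosome III had 58.1, I had 48.9, IV had 36.3, X had 32.7, II had 32.5 and V had 23.3.

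**Figure D5:**
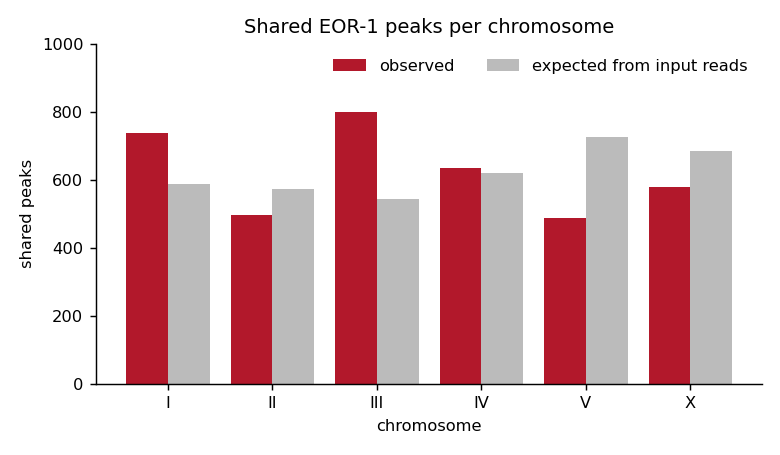
Number of shared regions (vertical axis) on each nuclear chromosome (horizontal axis), with red bars for the number observed and grey bars for the number its share of input reads gives. Observed numbers were above the input share on I (737) and III (801) and below it on II (496), V (488) and X (580).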

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

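The test of a weaker replicate 2 signal on chromosome X, and the repeats searched for among reads without a single placement, and their ratio over read classes, were chosen after the results were seen.

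X:11603799-11607670 was not among the replicate 2 peaks used here. Scaled by library totals, replicate 2 reads yet had a ratio of ChIP to input of 14.7 (10.9 to 19.9) there, and replicate 1 reads 24.2 (17.4 to 33.6). The replicate 2 ratio was 0.610 times that of replicate 1 (0.389 to 0.955), but a signal too weak to be listed is argued against: the binomial -log10 p of the region from its replicate 2 reads was 364, where the highest of the listed replicate 2 peaks had 151.005 by the same measure and their median was 2.48. For this measure input reads were scaled up by nuclear reads outside peaks and tested at equal odds. It is larger than the binomial test used for tiles would give, and serves only to compare regions. A candidate explanation is a p-value too small for double precision: the relation between deposited q-values and reads at 115 other replicate 2 peaks gave a -log10 q of 408. In replicate 1 the same relation gave 317.8 where the deposited value is 288.3, so such a prediction can be too high. The value of 408 is also an extrapolation, far beyond the other replicate 2 peaks, so it cannot settle the question. No biological explanation was tested.

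Reads without a single placement held repeats more often in ChIP than in the control libraries. Above, those with no placement served for the tag search, and those with 2 to 10 places helped to spell out the reference. A GA repeat of 8 units occurred 5.70 times as often in ChIP as in input in replicate 1 (95% interval 3.67 to 8.87, 189 reads against 22). In replicate 2 it was 6.12 times as frequent (4.07 to 9.20, 208 reads against 26). The CA repeat was 3.98 times as frequent in replicate 1 (2.61 to 6.08, 150 reads against 25) and 8.19 times in replicate 2 (5.34 to 13, 246 reads against 23). Read classes (no placement, over 10 places, 2 to 10 places) had unequal shares in the libraries, and over the classes the ratios were 6.45 (4.14 to 10.04) and 3.80 (2.55 to 5.67) for the GA repeat and 4.51 (2.95 to 6.90) and 5.23 (3.44 to 7.95) for the CA repeat, in replicates 1 and 2. The GA repeat in replicate 2 was 2.76 times as frequent among reads with over 10 places and 3.01 times among those with 2 to 10, and 47 reads stood against 3 among those with no placement.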

How the results depend on the processing

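The scaling by nuclear reads outside peaks, the block with library totals, the filter on ChIP reads alone and the summit as motif centre were chosen after the data were seen. Of 67 alternatives, 34 were counted as keeping the result, 33 as moving it, and 0 as reversing it. Kept means the same direction and side of the threshold where there is a test, and within 1.5 times for a count. A chromosome that passed in neither setting was counted as kept whatever its direction. Chromosome IV, which passed in none, went from a ratio of 1.02 to 0.974 with chromosome length as background. For a value with no test but an SD between replicates, it means within 1 SD. Peak shares and Spearman's rho have no such SD. Peak shares counted as moved lay outside the Wilson interval of the main share, and the alternatives for rho were counted as moved. The 34 include each chromosome's own ratio under each alternative, all counted as kept, as well as the count of chromosomes called. The chromosomes therefore enter more than once, which raises the number kept. Results that were kept include the 5 of 6 chromosomes called, the motif (more frequent at centres throughout, though 7.02-fold to 18.2-fold where it was 13-fold), reads in shared regions (3.73 and 4.26), the median log2 ratio (1.04 to 1.92) and depth around the tag (17.3). The cause of the changes below was not tested, except where fewer tiles or libraries entered the test.

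Tiles higher and lower in ChIP, 777 and 1061, became 1542 and 202 with library totals, 2725 and 131 with nuclear reads outside peaks, 1269 and 7001 with no filter on low counts, 14 and 213 with 500 bp tiles (10783 tested), 460 and 361 with the filter on ChIP reads alone, and 385 and 51 with the binomial test in both replicates. With the replicate block they became 1190 and 3130, and with the block and library totals 2651 and 1383; the block changed no other call, since no other result has one. More tiles were lower than higher at first, and the balance turned with library totals, with nuclear reads outside peaks, with the block and library totals, with the filter on ChIP reads alone, with the binomial test and without input replicate 1. Leaving out 1 library gave 0 to 366 higher and 0 to 703 lower, the lone library being assumed to vary like the other group: 0 and 0 by limma without ChIP replicate 1 (1326 and 2731 at unadjusted p under 0.05) and without ChIP replicate 2 (1519 and 1993), 106 and 56 without input replicate 1, and 366 and 703 without input replicate 2.

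Replicate 1 peaks shared, 74.7%, became 64.2% with 50% reciprocal overlap, 79.2% among the stronger 50% by q-value and 69.0% with centres within 200 bp; replicate 2 peaks, 67.7%, became 59.0%, 71.6% and 63.5%. Spearman's rho of q-values, 0.735, became 0.610 among the stronger 50%, and 0.157 for ratios. The 1538 more and 342 less frequent 8-mers became 852 and 267 within 50 bp, 595 and 84 among the stronger 50%, and 2080 and 617 around the summit. Promoter peaks, gene lists and unc-119 depth, with their alternatives, were not run. At this depth and n = 2, limma called 33% of simulated 4-fold changes and the binomial test 44%.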

Other observations

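The split of chromosomes into 3 equal parts, the retest of peaks in the other replicate, the listing of segments with extra input reads, the ratios over read classes, the count of tag reads with a single place and the test of ChIP reads in the inputs were chosen after the results were seen.

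Shared regions leaned to the middle of the autosomes, the gene-rich part of C. elegans chromosomes. Of 3157 autosomal regions, 1339 lay in the middle of 3 equal parts of their chromosome, 42.4% (40.7 to 44.1), where 36.7% of the input reads lay (exact two-sided binomial test, p = 5.36e-11). On X the share was 31.9% (28.2 to 35.8) against 35.1% of input reads (exact two-sided binomial test, p = 0.108). When the peaks of replicate 1 were tested by their reads in replicate 2, ChIP over input passed a binomial p under 0.05 in 32.9% of them with median-of-ratios scaling, 46.6% with library totals and 52.3% with nuclear reads outside peaks. Replicate 2 peaks passed in replicate 1 in 52.9%, 64.4% and 71% of cases. Few input reads enter each test, since nuclear shared regions held 11.2 and 14.9 reads per kb in inputs 1 and 2. Median peak widths were 304 and 305 bp. A peak that did not pass is therefore not shown to be absent from the other replicate.

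Input depth, relative to the median of a chromosome's 1 kb bins that held a read, was also raised elsewhere. At I:15062001-15070000, the end of chromosome I where the ribosomal RNA genes lie, it was 74.9 and 76.2 times that median. At III:8851001-8863000 it was 21.4 and 13.5 times, at I:3169001-3174000 it was 12.3 and 4.96 times, and at III:5226001-5259000 it was 4.66 and 4.76 times. Among reads without a single placement, taken over the classes by number of places, the telomere repeat was 1.40 (1.28 to 1.54) and 1.19 (1.08 to 1.32) times as frequent in ChIP as in input in replicates 1 and 2, and GAGACGCAG was 1.65 (1.47 to 1.86) and 1.64 (1.46 to 1.85) times as frequent.

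IV:4786001-4824000 had 16.7 and 20.3 times the median depth of the chromosome's 1 kb bins that held a read, in the inputs. Diverged genome copies collapsed onto 1 place are argued against. Reads with a mismatch differed from the flanks by -0.45 and 1.42 percentage points, with standard errors of 0.976 and 1.09. Copies that are identical or nearly so would add few mismatches or none, so this test cannot decide about them. GC content is argued against too, since windows of the same GC held at most 0.0617 of the segment's input density. Extra copies of the tagged clone in the strain are a candidate explanation that stays open, since of 3 reads with at least 12 bases beyond the tag, 1 had its single place in the segment, another had 22 places with 1 there, and the other had 5 places, none there. Whether the segment has extra copies in this strain was not tested in any other way.

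The shared regions held more input reads than their length gives, with densities 1.63 and 2.58 times those of their flanks in input 1 and input 2. GC content is argued against as the whole cause by windows of 100 bp either side of the centres. Their input density was 1.67 and 3.07 times that of windows outside all peaks. Against windows of the same GC it was 1.55 (1.51 to 1.58) and 3.02 (2.96 to 3.08) times. ChIP reads counted in the input libraries may account for part: input reads that copy a ChIP molecule made up 0.272 and 0.290 of the excess once the starts shared between the ChIP libraries were taken off, and 1.04 and 0.803 before. That correction decides the outcome, so this explanation stays open. Open chromatin at bound regions was not tested, nor was any other biological explanation.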
